A study of Mus musculus with 12 samples.

How the data were processed

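Total RNA was extracted with Trizol from brains of mice of 3 genotypes, and 60 micrograms per sample were labelled directly with Cy5 or Cy3, per the labels' protocols. The study hybridised extracts of the same genotype together on each of 6 spotted mouse cDNA arrays with 2 colours, per the design text, so that every sample is 1 colour of an array. The odd replicate numbers are Cy5 and the even ones Cy3 in the label field. For 2 samples, wildtype 3 and Gja9_null 1, the labelling text names the other dye, and the label field was followed. The design text gives 4 biological replicates per genotype, and each sample was taken as a separate animal, which the labels do not state. Data on other connexin knockouts that the design text mentions are not analysed here.

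The deposited values are log2 signals, each relative to the mean signal of its own sample. The scale was settled from the values, since 2 to the power of the value averages 1 in every sample over the probes with values, while base e does not give a common mean. Background correction, dye correction, the probe filter and any further normalization by the authors are not given in the sources used here. Of 28704 probes, 15261 have no value in any sample, 13443 have one in all samples and 0 in only some. Sample medians lay between -0.98 and -0.81, so no further centring was applied. Signal over background cannot be read from these values, and there is no depth for arrays, whose number limits the precision.

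Probes were named through the probe table of the array. Of the 13443 probes with values, 10356 have 1 gene, 560 have several and 2527 have none. Symbols were updated by gene number from a mouse RefSeq gene table, which matched 10263 probes, and the file's name was kept otherwise. No gene was named from a probe with several. Probes of 1 gene were averaged on the log2 scale, which gave 6427 genes, 2586 of them with at least 2 probes, and all other probes were tested alone, for 9514 features. The build behind the arrays is not given in the sources used here, and no coordinates are reported.

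The labels do not say which samples shared an array. By a rule fixed before the data were examined, the pairing was read from the correlation across probes of the difference between samples 1 and 3 (Cy5) with that between samples 2 and 4 (Cy3). It was 0.940 in wildtype, 0.933 in Gja9_null and 0.919 in Gja9_het, so samples 1 and 2 were taken to share an array, and samples 3 and 4 likewise. Replicate numbers do not pair samples across genotypes.

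Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 model over all 12 samples, with genotype and dye as terms and the array as a random block (duplicateCorrelation, consensus correlation 0.928). P-values were adjusted by Benjamini-Hochberg over all features, and an adjusted p under 0.05 was called. Gene lists fixed before the data were examined (32 lists) were tested with camera at a preset correlation of 0.01 where at least 5 genes were measured (23 lists), beside camera with an estimated correlation and fry, which took genotype and dye as terms. The prior gave 6.53 of the 14.5 degrees of freedom.

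Named genes follow a rule fixed before the data were examined: measured connexins and pannexins; per comparison the 10 higher and 10 lower called genes of largest change with an established symbol, filled to 5 by the smallest unadjusted p where fewer passed; from each list up to 4 genes of smallest p; and sex-linked markers. Genes named beyond the rule are given as chosen after their values were seen.

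The fit was tested on simulated data with the observed means, spread and array correlation, for Gja9_null against wildtype over 9514 features. It recovered 91% of 200 features changed by 2 log2 units and 3.5% of those changed by 1, with 13 and 0 false calls. With the 2 colours of each array averaged, it recovered 90.5% and 1%. In 5 simulations with no change, between 0 and 2 features were called. These simulations gave every feature the same array correlation and no effect of probe number, as the fit assumes. They therefore cannot test those assumptions. In the real data, the fit with the array block called 31 features and that on array means 2. Local centring subtracts from each sample the median deviation from the probe means over 50 probe numbers on either side. On simulated smooth array effects it lowered the SD of the error from 0.37 to 0.14 and kept 99.8% of a change of 2 log2 units.

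Alternatives fixed before the data were examined covered the array block, the array pairing, the replicate number as a block, the dye, normalization, the samples in the fit, dim probes, averaging of probes, the spread model, array weights, thresholds and leaving out each sample. Those chosen after seeing the data were local centring, array means, both together, leaving out the first Gja9_null array or the last 3 of 48 stretches of probe numbers, and camera on ranked statistics. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.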

Results

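Brain transcriptomes of 10-day-old C57Bl/6j mice were profiled on cDNA arrays in 3 genotypes, with 4 biological replicates in each: wildtype mice, mice lacking both copies of Gja9 (Gja9_null) and mice lacking 1 copy (Gja9_het). Gja9 in the labels is the gene now named Gjd2, which encodes connexin36, the main gap junction protein of neuronal electrical synapses. Extracts of 2 replicates of the same genotype, in opposite dyes, shared each array, so the 12 samples lay on 6 arrays and each genotype on 2. A value was present for 13443 of 28704 probes, and the same probes had values in all 12 samples. These gave 9514 features: 6427 genes, with clones of the same gene averaged, and single probes with no gene or several genes. Values are the log2 signal relative to each sample's mean signal. The number of arrays limits the precision of every comparison.

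The samples of 1 array were nearly alike. Across probes, the correlation between the 2 colours of an array lay between 0.986 and 0.991, while that between samples of the same genotype on different arrays lay between 0.865 and 0.922 and that between genotypes between 0.807 and 0.922. The median absolute difference between arrays of a genotype was 0.36 in wildtype, 0.43 in Gja9_null and 0.28 in Gja9_het, against 0.08, 0.10 and 0.07 between the 2 colours of an array. The labels do not say which samples shared an array, and the pairing was read from the values. The first Gja9_null array, taken to hold samples 1 and 2, stood apart. On the first principal component of the array means, which took 44.4% of the variance, it had a score of 54.6, and the other 5 arrays lay between -23.3 and 12.6. Array deviations followed the probe numbers in stretches. The median deviation per stretch of 598 probe numbers ranged from -1.35 to 0.48 on the first Gja9_null array and from -0.20 to 0.32 on the second Gja9_het array.

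**Figure D1:**
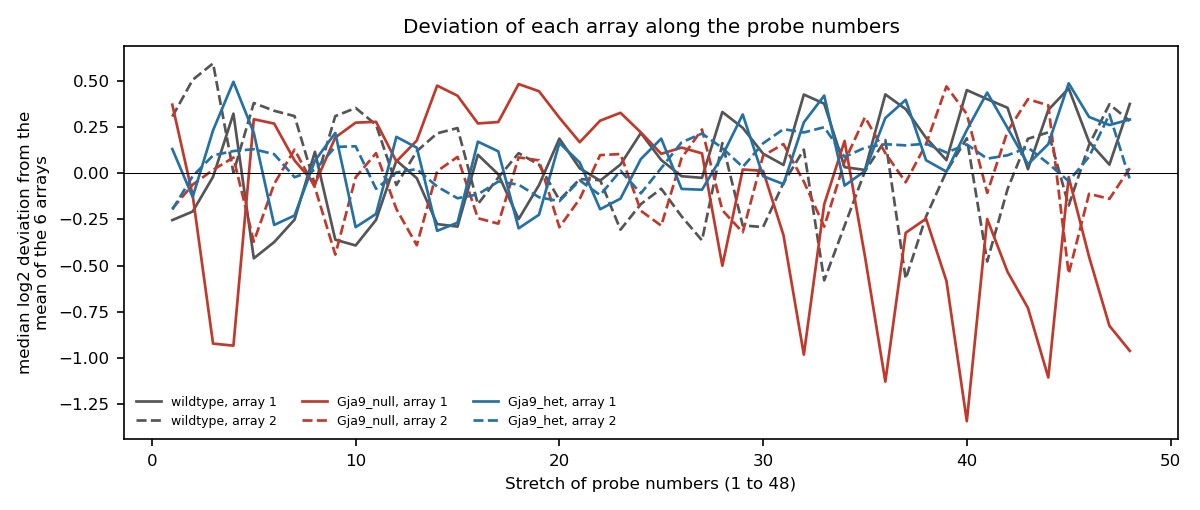
Median log2 deviation of each of the 6 arrays from the mean of all arrays (vertical axis) in 48 consecutive stretches of 598 probe numbers (horizontal axis), with 1 line per array. The first Gja9_null array falls to -1.35 in its lowest stretch, below the lowest value of every other array.

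The targeted gene could not be read out, because the probe table names 0 probes for Gjd2. Among connexins and pannexins, 2 of 23 listed genes were measured, and neither passed the test. Gja1, the main astrocytic connexin, differed from wildtype by -0.18 ± 0.41 log2 units (SE, n = 4 samples on 2 arrays per genotype) in Gja9_null and by -0.37 ± 0.41 in Gja9_het, with limma and Benjamini-Hochberg adjusted p of 0.919 and 1. Panx1, a pannexin channel gene, differed by -0.82 ± 0.36 in Gja9_null (adjusted p = 0.403) and by -0.20 ± 0.36 in Gja9_het. Its 2 clones disagreed in Gja9_null, at -0.11 ± 0.34 and -1.52 ± 0.55. Eif2s3y, the only measured gene of the sex-linked list, differed by 0.23 ± 0.86 in Gja9_null and 0.22 ± 0.86 in Gja9_het.

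The comparison of Gja9_null with wildtype asks which transcripts differ when Gja9 is lost completely. Slc7a6, an amino acid transporter gene, rose by 2.16 ± 0.43 log2 units in Gja9_null brains (SE, adjusted p = 0.0496, limma with Benjamini-Hochberg adjustment, 4 samples per genotype). Its 2 wildtype arrays lay apart, with means of 2.15 and 0.45, against 3.38 and 3.54 on the Gja9_null arrays. Irak1, a kinase of interleukin receptor signalling, rose by 2.03 ± 0.39 (adjusted p = 0.044), and Irgq, of the immunity-related GTPase family, by 1.51 ± 0.29 (adjusted p = 0.039). Cdk13, a kinase acting on transcription, fell by 2.51 ± 0.41, and Smarcad1, a chromatin remodelling ATPase, fell by 2.48 ± 0.41, both with an adjusted p of 0.0206. Ak8, an adenylate kinase gene, fell by 2.17 ± 0.35, and Rnaseh1, which cuts the RNA strand of RNA-DNA hybrids, fell by 1.89 ± 0.31.

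The other named genes that fell had log2 differences between -1.82 and -1.66. They were Myo9a, an unconventional myosin (-1.82 ± 0.32), Dmkn (-1.82 ± 0.34), Aagab (-1.79 ± 0.35), Gmds, an enzyme of GDP-fucose synthesis (-1.77 ± 0.31), Tmem176a (-1.66 ± 0.31) and Il20rb, a cytokine receptor subunit (-1.66 ± 0.33). Each called gene named so far, except Irgq, rests on 1 probe, so no second clone could be compared. In all, 31 of 9514 features passed at an adjusted p under 0.05, of which 11 were higher and 20 lower in Gja9_null. Of these, 14 carried a single gene, 3 of them higher. Beside the genes above, the 14 include Htr7 (-1.57 ± 0.29, limma adjusted p = 0.0372), named after its value was seen. The largest called difference was at a probe with no single gene, higher by 4.92 ± 0.52 (limma adjusted p = 0.0013). This probe was picked out after its value was seen. Genotype differs only between arrays, while this test also takes degrees of freedom from the 2 colours of an array. Ak7 (2.24 ± 0.50, adjusted p = 0.0859) and Samhd1 (1.79 ± 0.40, adjusted p = 0.0935) led the named genes with higher values that did not pass. At an unadjusted p under 0.05, 229 features were higher and 877 lower, where the nominal rate would give 476 in all. In the simulations with no change, between 5.46% and 6.23% of features fell under this threshold. The median difference over all features was -0.10.

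**Figure D2:**
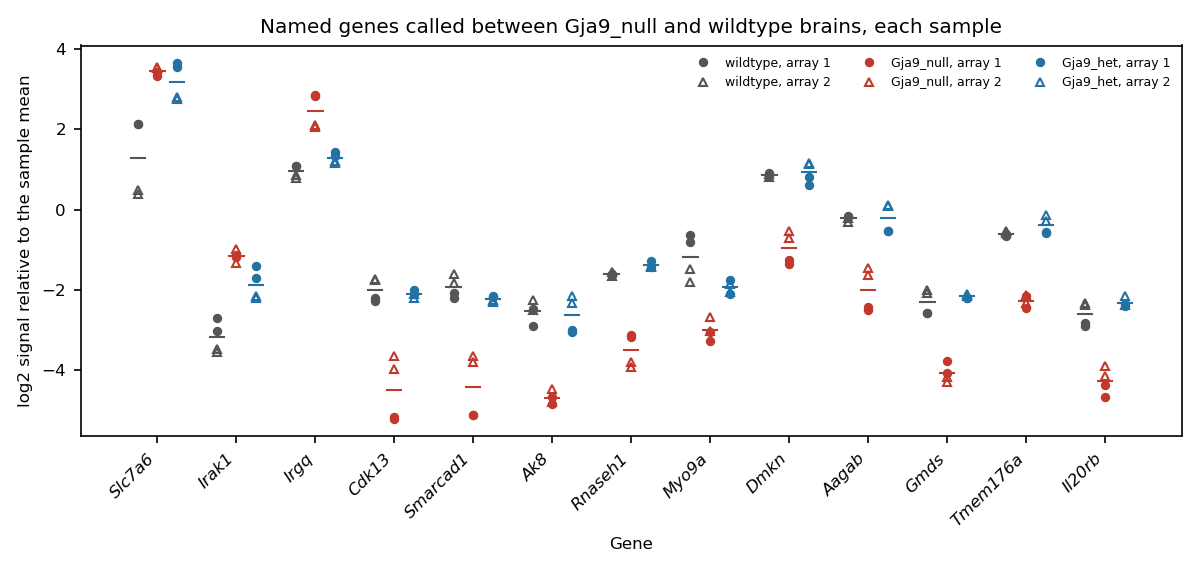
Log2 signal relative to the sample mean (vertical axis) of the 13 named genes with the largest called differences between Gja9_null and wildtype (horizontal axis), for each of the 12 samples. Colours mark the genotype, filled circles the first and open triangles the second array of a genotype, and short lines the mean of 4 samples. Cdk13 has a mean of -1.99 in wildtype, -4.50 in Gja9_null and -2.10 in Gja9_het.

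The probes of the lower genes were clustered. Of the 20 lower features, 15 lay in the last 3 of 48 stretches of probe numbers, which hold 5.34% of all features, against 1 of the 11 higher features. These stretches were picked because the lower features lay there, so no p-value is given for it. When each sample was centred locally along the probe numbers, an alternative chosen after seeing the data, 10 of the 11 higher and 5 of the 20 lower features remained called. The difference in Irak1 was then 2.67 and in Irgq 1.37, and both stayed called, while Slc7a6 stood at 1.87 (adjusted p = 0.0512). Myo9a (-1.98) and Cdk13 (-1.08) also stayed called. Htr7 (-1.26), Smarcad1 (-0.98), Ak8 (-0.98), Rnaseh1 (-0.80), Dmkn (-0.59), Tmem176a (-0.41), Aagab (-0.35), Gmds (-0.27) and Il20rb (-0.25) did not. Irgq rested on 1 of its 2 clones, which differed by 2.68 ± 0.43 and 0.35 ± 0.34 when tested alone. With the 2 colours of each array averaged, 2 features were called, both higher and neither among the 14 genes named above as called. Quantile normalization left 5 higher and 0 lower, cyclic loess 8 and 0, and median centring 13 and 10. Without the first Gja9_null array, 51 features were called, 5 higher and 46 lower, and without wildtype sample 3, 13 were.

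No fixed gene list stood out between Gja9_null and wildtype. With camera at a preset correlation, 0 of 23 lists with at least 5 measured genes passed, the smallest adjusted p being 0.732, and 0 passed with an estimated correlation or with fry. None of the 408 list entries passed over all genes tested. Among the neuronal lists, the 9 pan-neuronal markers had a median difference of -0.01, and Nefm, a neurofilament gene, was the 1 member called when adjusted over the list alone (-1.74 ± 0.53, adjusted p = 0.0468 over the list and 0.217 over all genes). The median was -0.47 over 7 GABAergic interneuron markers, among them Maf at -1.08 ± 0.43, and 0.17 over 5 forebrain and cortical neuron markers. It was -0.13 over 8 genes of glutamate receptors and the excitatory synapse, 0.03 over 10 synaptic vesicle genes and -0.01 over 7 voltage-gated ion channel genes. The last 5 of these lists had no member called, over all genes or when adjusted over the list alone.

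Glial and vascular markers did not separate Gja9_null from wildtype either. The 10 astrocyte markers had a median of 0.12, with Slc1a3, a glutamate transporter, at 0.90 ± 0.31 and Fabp7 at 1.66 ± 0.67. The median was -0.45 over 8 oligodendrocyte and myelin markers, -0.17 over 8 microglia and immune markers, -0.10 over 7 endothelial and pericyte markers and -0.10 over 19 genes of meninges and extracellular matrix. The 17 junction and adhesion genes had a median of 0.03, with Cdh1 at -1.46 ± 0.42 and Nectin2 at -1.12 ± 0.39. In each of these lists 0 members were called, over all genes or adjusted over the list alone.

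Medians of the housekeeping lists lay between -0.27 and 0.13. The 57 cytosolic ribosomal protein genes had a median below 0.01 in size, with Rpl17 at -1.71 ± 0.51 and Rpl29 at -0.89 ± 0.33. The 56 genes of mitochondrial oxidative phosphorylation had a median of -0.08, with Ndufa6 at -1.56 ± 0.43 and Sdhb at 0.74 ± 0.33. Of 30 proteasome and ubiquitin genes, with a median of 0.01, Psmc6 was the 1 called when adjusted over the list alone (-1.53 ± 0.40, adjusted p = 0.048 over the list and 0.155 over all genes). The 27 chaperone and stress genes had a median of -0.27, with Cct8 at -1.04 ± 0.33 and Atf4 at -0.88 ± 0.33. The median was 0.00 over 27 tubulin, actin and motor protein genes, 0.06 over 15 genes of glycolysis and lactate, -0.09 over 18 of calcium and calmodulin signalling and 0.13 over 20 proliferation genes. It was 0.05 over 11 apoptosis genes, 0.03 over 10 circadian clock genes, with Bhlhe40 at 0.97 ± 0.33, and -0.12 over 22 genes near Gjd2 on its chromosome, with Rtf1 at -0.77 ± 0.30 and Rmdn3 at 0.67 ± 0.31. In the lists other than proteasome and ubiquitin, 0 were called when adjusted over the list alone.

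Lists with fewer than 5 measured genes had no set test. Alas2, the erythroid enzyme that starts haem synthesis, was called in Gja9_null against wildtype when adjusted over the 3 measured erythroid genes alone (-1.45 ± 0.34, adjusted p = 0.0021 over the list and 0.107 over all genes), while Hbb-b1 (0.39) and Hba-a2 (0.17) were not, and the list had a median of 0.17. Ache, the acetylcholinesterase gene, was called over the 4 monoamine and cholinergic genes alone (-1.20 ± 0.32, adjusted p = 0.008 over the list and 0.161 over all genes), where the median was -0.32. No member was called over the list alone among the oligodendrocyte precursor markers (4 measured, Pdgfra at -0.84 ± 0.34), the choroid plexus and ependyma markers (4, Ttr at 0.50), the cerebellar Purkinje and granule neuron markers (4, Calb1 at -0.58) or the GABA and glycine receptors (2, Gabra3 at -0.46). The choroid plexus and ependyma list had a median of -0.06, against 0.50 for Ttr. The only measured immediate early gene, Fosl2, differed by 0.00.

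The comparison of Gja9_het with wildtype asks what partial loss of Gja9 does. No feature passed with limma and Benjamini-Hochberg adjustment, where the smallest adjusted p was 1. At an unadjusted p under 0.05, 159 features were higher and 49 lower, fewer in all than the 476 of the nominal rate. The named genes of smallest unadjusted p, none of which passed, were Slc7a6 (1.90), Numb, a regulator of Notch signalling (1.25), Sema3a, an axon guidance ligand (1.38), Oas1a (1.73) and Pxn (1.04) with higher values. Those with lower values were Tmem63a (-0.99), Uqcr10, of the respiratory chain (-1.15), Dmtn (-1.16), Eapp (-0.73) and Tmem88 (-0.71). Without the array as a block, which counts the 2 colours of an array as independent, 70 features were called.

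The gene lists gave 0 calls of 23 between Gja9_het and wildtype with camera, the smallest adjusted p being 0.429, and 0 with an estimated correlation or fry. The 20 proliferation genes had a median of 0.19, with Mcm4 at 0.84 ± 0.32, and the 27 tubulin, actin and motor protein genes one of -0.12. Medians of the 23 lists lay between -0.17 (oligodendrocyte and myelin markers) and 0.19. Fabp7 differed by 1.75 ± 0.67, Cct6a by -0.85 ± 0.35 and Eif2ak4, near Gjd2, by 0.88 ± 0.37. No member of any list was called over all genes or when adjusted over the list alone.

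Gja9_null and Gja9_het, compared directly, differed in 26 features, of which 1 was higher and 25 lower in Gja9_null and 13 carried a single gene. Il17rc, an interleukin receptor gene, fell by 2.53 ± 0.44 (adjusted p = 0.0345, limma with Benjamini-Hochberg adjustment), and Sbf1 fell by 2.37 ± 0.40 (adjusted p = 0.028). Ces2a, a carboxylesterase gene, fell by 2.25 ± 0.41 (adjusted p = 0.0394). Cdk13 (-2.40), Smarcad1 (-2.19), Rnaseh1 (-2.12), Ak8 (-2.07), Il20rb (-1.94), Gmds (-1.91) and Dmkn (-1.89) were also called lower here, in a comparison that shares the Gja9_null arrays with the one against wildtype. The higher values of Tmem63a (1.67, adjusted p = 0.0652), Slc1a3 (1.39, adjusted p = 0.0724), Irgq (1.18), Rad23b (1.11) and Rnf114 (1.47) did not pass. Quantile normalization, cyclic loess, median centring and averaging the colours of each array each left 0 calls, and so did leaving out the dimmest 25% of probes, the last 3 stretches (chosen after seeing the data) or any 1 of wildtype 3 and Gja9_het 2, 3 and 4. Local centring, chosen after seeing the data, called 134 features, 45 higher and 89 lower, and kept the 1 higher and 10 of the 25 lower features, among them Il17rc (-1.33), Sbf1 (-1.65) and Ces2a (-1.90). Of the genes named here, the 7 called against wildtype too did not stay called: Ak8 stood at -1.04, Rnaseh1 at -0.96, Cdk13 at -0.84, Dmkn at -0.66, Smarcad1 at -0.53, Il20rb at -0.35 and Gmds at -0.23.

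No list was called between Gja9_null and Gja9_het, the smallest camera adjusted p being 0.247 for tubulin, actin and motor proteins (27 genes, median 0.08), with Kif1a, an axonal motor, at 1.45 ± 0.45. Cytosolic ribosomal proteins had a median of 0.03, with Rpl37a at 1.01 ± 0.29. Adjusted over the list alone, 1 gene was called in each of 5 lists and 0 in the others, and none of them passed over all genes: Cdh1 (-1.92 ± 0.42) among junction and adhesion genes, Slc1a3 (1.39 ± 0.31) among astrocyte markers, Tek (-1.07 ± 0.30) among endothelial and pericyte markers, Alas2 (-1.71 ± 0.34) among erythroid genes and Ache (-0.94 ± 0.32) among monoamine and cholinergic genes. The median of a list and the direction of its camera test differed in sign for 11 of 23 lists here. They did so for 7 between Gja9_null and wildtype and for 2 between Gja9_het and wildtype. Camera compares a list with all other features, which can set its direction apart from the median. The median also differed in sign from the list's own mean, for 6, 6 and 5 lists in the same order.

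The limma F-test over the 3 genotypes passed 31 features at an adjusted p under 0.05, and 1040 at an unadjusted p under 0.05. Array means left 0, quantile normalization 1, cyclic loess 3 and leaving out the last 3 stretches 5, while leaving out each sample in turn gave between 10 and 33 and local centring 84.

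Both comparisons with wildtype share the same 4 wildtype samples. Across features, their log2 differences correlated with r = 0.24 and had the same direction in 53.7% of features, where unchanged groups simulated against shared controls gave 0.50 and 66.6%. The simulated values follow from independent groups of equal spread, whatever the data, so falling below them was not read as an effect of genotype. Features are not independent replicates. The covariance was 0.04, against 0.08 in the simulation, a difference of -0.03. After local centring, chosen after seeing the data, the covariance was 0.0358 against 0.0331, while r (0.28 against 0.50) and the share in the same direction (56.6% against 66.7%) stayed below the simulation. With 1 wildtype array given to each comparison, r was -0.22 or -0.13, depending on the array, and -0.03 or -0.10 after local centring. At an unadjusted p under 0.05, 41 features were higher in both and 11 lower in both. Lists of the same length from 100 simulations of unchanged groups against shared controls, added after the counts were seen, gave means of 38.3 (26 to 52) and 28.6 (19 to 38). The 41 lay within the simulated range and the 11 below it. All 11 features called higher in Gja9_null had a Gja9_het mean between those of wildtype and Gja9_null, with a median difference from wildtype of 1.90 in Gja9_het and 3.26 in Gja9_null. Of the 20 called lower, 11 had a Gja9_het mean between the other 2, and their median difference from wildtype in Gja9_het was -0.07, against -1.80 in Gja9_null. The same simulations gave means of 9.88 (8 to 11) of 11 and 17.4 (12 to 20) of 20. The count for the higher features lay within the simulated range, so by itself it gives no evidence for a graded effect. The simulated groups were unchanged in both genotypes, so the count cannot argue against a graded effect either. The count for the lower features lay below the range. These simulations assume groups of equal spread, while the median difference between arrays was 0.36 in wildtype, 0.43 in Gja9_null and 0.28 in Gja9_het. Counts below the simulated range were therefore not read as an effect of genotype.

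Variability was described without a test, since each genotype has 2 arrays. The median SD over features among the 4 samples was 0.22 in wildtype, 0.27 in Gja9_null and 0.17 in Gja9_het. After local centring it was 0.16, 0.14 and 0.16, so that Gja9_null went from the highest to the lowest of the 3.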

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

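The tests of probe number, of clones and of the Gja9_null arrays below, apart from the share of all called features kept by local centring, the share of dim called features and the comparison of bright with dim genes, were chosen after the result was seen. The tests on other splits of the arrays were chosen before.

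Of 105 groups of 4 samples examined for a sample far from the others, 2 stood out. For 4 independent values, a rate of about 1 in 20 groups would give 5.25. The 2 colours of an array are nearly alike, so that rate does not hold here and the 2 cannot be set against it. In Rnaseh1, Gja9_het sample 2 (-1.27) lay apart from samples at -1.42, -1.40 and -1.42, with a gap of 0.853 of the range. In Eif2s3y, wildtype sample 2 (0.09) lay apart from the others, of which the nearest was at -0.83, with a gap of 0.842 of the range. No explanation was tested for either.

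The first pattern is the set of 31 features called between Gja9_null and wildtype. After local centring along probe numbers 15 of the 31 stayed called in the same direction, just under the share fixed beforehand for a position effect, and the directions parted: 5 of the 20 lower features stayed and 10 of the 11 higher ones. Position on the array may therefore account for most of the lower calls, whose median difference went from -1.80 to -0.98, and argues little for the higher ones, whose median went from 3.26 to 3.47. Dim spots on the first Gja9_null array stay open as a cause of the lower calls. Of the 31 called features, 11 were both lower and in the dimmest 20% of features, a share between the bounds set. With the dimmest 25% of probes left out, 6 higher features and 1 lower were called. That fit drops dim features whatever their cause, so it cannot decide. In the dimmest 20%, 293 features were lower and 13 higher at an unadjusted limma p under 0.05. The brightest 20% held 96 lower and 94 higher. The first Gja9_null array deviated by -0.39 in the dimmest 20% and by 0.01 in the brightest 20%. With that array left out, 10 of the 20 lower features stayed called, so these 10 calls did not need it. That fit called 46 lower in all, with 1 array assumed to vary like the others. All 20 were picked as low over both arrays. A low second array is thus partly built into this count, as into their median of -1.71 on it. A difference due to the genotype itself stays open for the higher features and for the lower ones that stayed.

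The second pattern is that differences between the 2 arrays of a genotype follow probe number. Neighbouring probe numbers correlated at 0.745 in the difference between the Gja9_null arrays, 0.572 in wildtype and 0.263 in Gja9_het. An order of clones by tissue or function is argued against, because the mean signal over all samples correlated at only 0.0855 between neighbours. After a running median was taken off, the correlation at 26 probe numbers apart exceeded that at 13 apart by 0.164, which is consistent with rows of spots on the slide. The layout itself is not given in the sources used here, and no biological explanation was tested.

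The last pattern is that fold changes of 2 clones of 1 gene hardly correlate: over 2586 genes the correlation of the Gja9_null difference was 0.0508, while that of the mean signal was 0.431. Local centring left it at 0.0436, and the brightest of 3 equal groups of genes exceeded the dimmest by only 0.033. Either value could rise only where transcripts truly differ, since clones of unchanged genes share no difference to uncover. Position along the probe numbers and noise of dim spots therefore both stay open. With each probe tested alone after local centring, the 16 called higher probes of genes with other clones had a median of 1.25 and the 27 other clones one of -0.0326 ± 0.08 (SE), and for the 7 called lower the values were -1.45 and 0.14 ± 0.18 over 11 other clones. A change of the whole named transcript is argued against for these probes as a set, and wrongly assigned clones, transcript variants and chance in single probes stay open, as untested. Of the 3 named genes called higher with clones averaged, only Irgq has a second clone, at 0.3501, which is too few to tell.

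Other splits of the arrays were too few for a share under 0.05. With arrays kept whole there are 3 splits for each pair of genotypes, and the real one called 31, 0 and 26 features for Gja9_null against wildtype, Gja9_het against wildtype and Gja9_null against Gja9_het, against at most 0 in the others. The number of splits with as many calls was 1, 3 and 1. For the 3 genotypes, 2 of 15 splits gave as many as the real 31, and the highest other gave 53. That split kept the Gja9_null arrays together and mixed wildtype with Gja9_het arrays.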

How the results depend on the processing

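Local centring, array means, leaving out an array or stretches and the ranked set test were chosen after seeing the data. No called gene named in the text changed direction in an alternative where its value was recorded, which was so for 8 of 25 called values with the dimmest 25% of probes left out and for 0 without the last 3 stretches. Counts are given as Gja9_null against wildtype, Gja9_het against wildtype, Gja9_null against Gja9_het and the 3 genotypes together, with 31, 0, 26 and 31 as reported, and only those that moved by over 1.5 times are printed. Except where a smaller set of samples or features explains it, the cause was not tested.

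Without the array block the counts were 1464, 70, 2119 and 1997, and pairing the samples of an array the other way left no positive correlation, so no block was fitted and the same counts came out. With the replicate number as a block, and no array block, they were 1770, 135, 2490 and 2396. These fits treat the 2 colours of an array as independent, and the replicate numbers only name samples. No gene list changed its call under the replicate block.

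Without the dye term, 64 features differed between Gja9_null and Gja9_het and 49 among the 3 genotypes. Median centring gave 0 and 19 for these. For Gja9_null against wildtype, Gja9_null against Gja9_het and the 3 genotypes, quantile normalization gave 5, 0 and 1, cyclic loess 8, 0 and 3, and leaving out the dimmest 25% of probes 7, 0 and 8. With only the 2 genotypes compared in the fit, the pairs gave 3 and 1. Each probe alone gave 17 and 0 for the 2 comparisons of Gja9_null, and median SDs of 0.25 in wildtype, 0.30 in Gja9_null and 0.20 in Gja9_het. A trended, robust spread gave 5 for Gja9_null against Gja9_het and 18 for the 3 genotypes, and array weights, whose estimation stopped before full convergence, 14 for Gja9_null against wildtype and 9 for the 3 genotypes. An adjusted p under 0.1 gave 56, 119 and 59. An unadjusted p under 0.05 with a 1.5-fold change gave 1100, 206 and 1419 for the 3 pairs.

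Local centring gave 56, 1, 134 and 84, median SDs of 0.16 in wildtype and 0.14 in Gja9_null, and 3 gene lists called between Gja9_null and Gja9_het, all lost with an estimated correlation (adjusted p = 0.686 for each). Array means gave 2, 0 and 0 for the comparisons with Gja9_null and the 3 genotypes. Both together gave 0, 0 and 0 and 1 list called, cytosolic ribosomal proteins (adjusted p = 0.0219), also lost with an estimated correlation (adjusted p = 0.766). Leaving out the first Gja9_null array gave 51, 95 and 55, with Gja9_null then resting on 1 array assumed to vary like the others. Leaving out the last 3 stretches gave 6, 0 and 5. Dye read from the labelling text and the filter on missing values moved no count by over 1.5 times, and the latter removes no probe. A pseudocount was not run, since values are already log2.

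Leaving out each sample in turn gave between 13 and 25 for Gja9_null against wildtype, 0 and 20 for Gja9_null against Gja9_het and 10 and 33 for the 3 genotypes, and 0 for Gja9_het against wildtype. The correlation of the comparisons lay between 0.219 and 0.262. For Gja9_null against wildtype the count fell by over 1.5 times without wildtype 1 (15), 3 (13) or 4 (15), Gja9_null 2 (17) or 4 (19) and Gja9_het 1 (20). For Gja9_null against Gja9_het it did so without wildtype 1 (13), 2 (13), 3 (0) or 4 (17), Gja9_null 2 (14) or 4 (16) and Gja9_het 1 (13), 2 (0), 3 (0) or 4 (0). For the 3 genotypes it did so without wildtype 2 (20) or 3 (14), Gja9_null 2 (18) and Gja9_het 1 (18), 2 (19), 3 (10) or 4 (17). Median SDs lay between 0.21 and 0.24 in wildtype, 0.25 and 0.27 in Gja9_null and 0.16 and 0.19 in Gja9_het. Signal over background is not known for these arrays.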

Other observations

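All values in this part come from local centring along the probe numbers, chosen after the results were seen, and the genes were chosen after their values were seen. In Gja9_null against wildtype, limma with Benjamini-Hochberg adjustment then called genes that had not passed without it. Naprt, an enzyme of NAD synthesis, was higher by 2.98 ± 0.51 (adjusted p = 0.0175), Fcgbp by 2.29 ± 0.35 (adjusted p = 0.0104), Tmed3, of the secretory pathway, by 2.19 ± 0.37 (adjusted p = 0.0175), Ak7, an adenylate kinase gene, by 2.17 ± 0.38 (adjusted p = 0.0209) and Samhd1, a dNTP hydrolase gene, by 1.66 ± 0.26 (adjusted p = 0.0109). Without local centring their adjusted p lay between 0.0859 for Ak7 and 0.316 for Naprt. Rest, a repressor of neuronal genes, stood at -0.93 ± 0.18 (adjusted p = 0.0387) and Lrfn4, a synaptic adhesion gene, at -1.75 ± 0.31 (adjusted p = 0.0217). With the colours of each array averaged as well, 0 features were called.

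Between Gja9_null and Gja9_het, local centring gave higher values for cytosolic ribosomal proteins (57 genes, median 0.25, camera adjusted p = 0.026), proteasome and ubiquitin genes (30 genes, median 0.20, adjusted p = 0.0497) and tubulin, actin and motor proteins (27 genes, median 0.26, adjusted p = 0.0497). None of these calls held with an estimated correlation (adjusted p = 0.686 for each) or with fry, where the adjusted p was 0.618, 0.178 and 0.171.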
